A study of Mus with 8 samples.

How the data were processed

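Total RNA of interscapular brown adipose tissue was measured on 8 Affymetrix arrays, 1 per mouse, of 4 mice labelled as Hilpda KO and 4 labelled as wild type. Per the labels, RNA was isolated with a column kit, biotinylated with the WT Terminal Labeling Kit and hybridized without technical replicates. The design text names a Clariom S array, whereas the value table holds 72688 probe sets, of which 6732 are controls, more than that design would need; the array type is not settled here. Groups and replicate numbers were taken from the sample labels.

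The deposited values are log2 expression values. Per the labels, the authors made them by RMA in Affymetrix Expression Console with core-exon analysis, and the design text names Transcriptome Analysis Console. Versions, annotation and genome build are not given in the sources used here. The log base was read from the values, since the highest value on 4 arrays, 19.93, is log2 of 1e+06. No scanner files were used here, so the normalization could not be repeated from the probes. The number of arrays limits the precision, and signal over background was judged from 1088 olfactory receptor genes, whose median was 3.26 to 3.85 and whose 95th percentile was 3.81 to 4.87.

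Gene names came from the platform annotation. Of the 65956 probe sets that are not controls, 31258 had 1 gene, 1492 had several and 33206 had no name here. Symbols were updated through gene identifiers in a RefSeq table of assembly GRCm38.p6, which matched 31256 of the 31258. That table served only for names and for which genes neighbour each other. A gene with more than 1 probe set (442 genes) was represented by the probe set with the highest mean, which left 30701 genes. The other 34698 probe sets were tested separately.

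The arrays form 2 sets. In replicates 1 and 2 of both groups (set 1) the median of named genes was 3.93 to 3.99, and in replicates 3 and 4 of both groups (set 2) it was 4.92 to 4.97, with a lower highest value. RMA brings arrays of one run to a common distribution, so the sets were treated as normalized apart. Levels are compared within a set or with the set balanced over the groups. Genes within 0.1 of the highest value on an array were treated as saturated there.

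Before the data were examined, the test was fixed as limma (version 3.58.1 in R 4.3.3) with lmFit and eBayes on KO minus wild type over all arrays without a block and without a filter, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Hilpda was also tested by a two-sided exact permutation test over 70 arrangements, whose smallest p is 0.0286, and over 36 arrangements within the sets, whose smallest p is 0.0556. The within-set exact permutation p was 0.278. The 28 gene lists, 1 for each of the pathways and cell types described, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation, with fry and with an exact permutation of the list mean. Between 12 and 71 members of a list were measured. Genes within 10 Mb of Hilpda were counted against all others by Fisher's exact test.

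The named genes followed a rule fixed before the data were examined. Hilpda came first, then up to 12 genes per direction with the largest difference among those that passed and whose groups did not overlap, filled to 10 by unadjusted p among genes with a difference of at least 0.3 and a level above the median of all genes. The 4 members with the smallest unadjusted p were taken from each list described, with 12 fixed reference genes. Predicted, olfactory, vomeronasal and histone genes were passed over (0 on the KO-higher and 2 on the KO-lower side). For the difference between the sets, 12 genes per direction with the largest change were taken, and 15 genes were passed over. The members of the fixed lists and the genes near Hilpda that passed there, and Dbp in set 2, were named after their values were seen.

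Replicate numbers are shared by the groups. The deviations of same-numbered arrays from their group means correlated at 0.701, 0.473, 0.479 and 0.61 for replicates 1 to 4. The highest value of each KO array with a wild type array of another number was 0.517, 0.616, 0.628 and 0.531. It was above the same-numbered value for replicates 2 and 3, so a pairing by number is not shown. With the set difference removed the same-numbered values were 0.107, 0.107, -0.0891 and -0.0891, so the shared part lies between the sets. The fit with the replicate number as a block called 0 genes.

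The set as a block, the differences within each set, the test of the difference between the sets, and the skeletal muscle score were added after the data were examined. So were 2 lists of liver genes (12 whose values had been seen and 49 others) and lists of sex-linked genes (Xist, 3 broadly expressed Y-linked genes and 4 mainly of testis). Of the last list Zfy1, Zfy2 and Usp9y read 3.16 to 4.24 and Sry 5.07 to 7.31. Alternatives fixed beforehand were a filter on low values, eBayes with trend and robust settings, ordinary least squares, quantile normalization, median centring, array weights, every probe set on its own, other thresholds, and leaving out each array.

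The tests were checked on simulated arrays of 30701 genes with the measured set means and the spread within set and genotype, 100 genes changed per size. For KO against wild type no effect that differs between the sets was simulated, so the recovery with a block is overstated where such effects occur. Without a block 0 of 100 genes changed by 2 on the log2 scale were recovered. With the set as a block 73 and 97 of 100 changed by 1 and 2 were recovered with 13 false calls, with the replicate block 62 and 91 with 4 false calls, and for the difference between the sets 14 and 67 with 5 false calls. A glycolysis list shifted by 0.5 had a camera adjusted p of 1.43e-38 without a block, with 3 other lists called, and of 2.48e-27 with the set as a block, with 0 others called. Genes were simulated independently of each other, so false calls of lists with correlated members were not checked. In the data the estimated correlation with the set as a block was 0.828 for skeletal muscle markers and 0.0109 for glycolysis. Annotation and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.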

Results

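Transcript levels were measured in interscapular brown adipose tissue, the heat-producing fat depot between the shoulder blades, of C57BL/6 mice. Arrays of 4 mice labelled as lacking Hilpda were set against arrays of 4 wild type mice. Hilpda encodes a small protein of lipid droplets that is known to inhibit adipose triglyceride lipase, the enzyme encoded by Pnpla2. The labels call all mice female and describe the arrays as separate animals without technical replicates. After probe sets were reduced to 1 per gene, 30701 genes were compared on the log2 scale. The number of arrays, 4 per group, limits the precision of every value.

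The arrays fell into 2 sets that the labels do not mention. Replicates 1 and 2 of both groups (set 1) shared a highest possible value of 19.93, and replicates 3 and 4 of both groups (set 2) ended between 19.68 and 19.77. Between the sets, 27379 genes differed at an adjusted p under 0.05 in limma, and the first principal component, with 85.6% of the variance, parted them. Each set holds 2 arrays of each genotype, so the counts of genes and lists below are also given with the set as a block and within each set.

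Over all arrays Hilpda itself was not lower in those labelled KO by more than the spread. Its value was 4.98 ± 0.66 (SD, n = 4) in the arrays labelled KO and 5.14 ± 0.94 (SD, n = 4) in wild type. The difference was -0.16 (two-sided exact permutation p = 0.629 over 70 arrangements). Array by array, the values were 4.45, 4.37, 5.60 and 5.51 in KO replicates 1 to 4, and 4.37, 4.28, 6.00 and 5.92 in wild type replicates 1 to 4. The difference was 0.09 (SE 0.10) within set 1 and -0.40 (SE 0.10, limma adjusted p = 0.144) within set 2, where both KO values lay below both wild type values. Hilpda (gene 69573, chromosome 6) stood between the 56.7th and the 62.3rd percentile of all genes and near the 99th percentile of olfactory receptor genes, taken here as a group of mostly low signal. Where its probe set lies relative to the deleted part is not given in the sources used here. The level goes with the labels in set 2 and does not differ in set 1, and directions below refer to arrays labelled KO.

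Transcripts of other tissues varied between arrays. Albumin (Alb), the main secreted protein of liver, read 19.23 and 15.81 in KO replicates 1 and 2, 14.51 and 10.03 in wild type replicates 1 and 2, and 4.79 to 5.23 in the 4 arrays of set 2. The median of 49 further liver genes was 7.14, 5.25, 5.05 and 4.31 on the same 4 arrays of set 1, and 4.09 to 4.18 in set 2. Skeletal muscle genes, averaged over 33 markers, read 6.17, 8.19, 5.91 and 9.43 in KO replicates 1 to 4, and 7.43, 7.02, 9.80 and 8.58 in wild type replicates 1 to 4. The Y-linked genes Uty and Eif2s3y read 9.31 to 10.93 and 8.53 to 11.01, and the lowest of 3 such genes, Kdm5d, lay at least 3.67 above the olfactory receptor median on every array. Xist, the X-inactivation transcript of female cells, read 3.49 to 4.10. These sex-linked values go against the label of female mice on all 8 arrays and did not separate the genotypes.

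**Figure D1:**
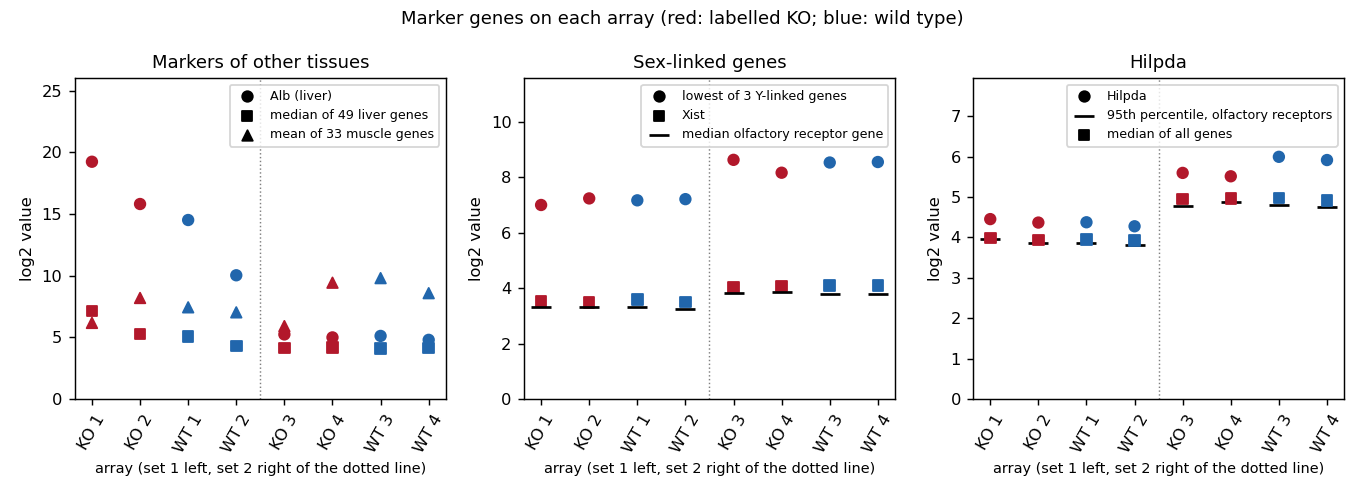
Log2 values of marker genes on each of the 8 arrays, red for arrays labelled KO and blue for wild type, with set 1 left and set 2 right of the dotted line; black dashes give olfactory receptor genes as background. Alb ranged from 10.03 to 19.23 in set 1 and from 4.79 to 5.23 in set 2, Xist stayed at 4.10 or less on every array, and Hilpda lay between 4.28 and 6.00.

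The comparison of KO with wild type asked which transcripts of brown fat differ when Hilpda is lost. No gene passed, and the smallest unadjusted p values belonged to Ddit4 and Herpud1, both higher in the arrays labelled KO. Ddit4, a stress-induced inhibitor of mTORC1 signalling, read 11.82 ± 1.02 in KO and 9.73 ± 0.66 in wild type (SD, n = 4 each), a difference of 2.09 (SE 0.53; 3.05 within set 1 and 1.13 within set 2). Herpud1, a component of protein degradation at the endoplasmic reticulum, read 14.92 ± 0.72 against 13.23 ± 0.71, a difference of 1.69 (SE 0.45; 1.79 and 1.59 within the sets), with all 4 KO values above all 4 wild type values. Mc5r, a melanocortin receptor, differed by 1.51 (SE 0.48), and Gadd45g, a growth arrest and DNA damage gene, by 1.15 (SE 0.41). Cebpa, a transcription factor of adipocyte differentiation, was at 11.12 ± 0.98 in KO and 12.34 ± 0.24 in wild type, a difference of -1.23 (SE 0.45; -1.69 and -0.76 within the sets).

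The KO-higher side was represented by the 10 genes with the smallest unadjusted p among those above the median level, and the other 6 of them were genes with known liver expression or pseudogenes of such genes. Cyp4a31 and Cyp4a32, fatty acid hydroxylases, differed by 1.57 (SE 0.51) and 1.98 (SE 0.70), and Hgd, a tyrosine-degrading enzyme of liver, by 1.34 (SE 0.46). The major urinary protein pseudogenes Mup-ps14 and Mup-ps6 differed by 1.31 and 1.04, and Mup-ps10 read 6.04 ± 1.15 in KO and 4.54 ± 0.43 in wild type. Albumin was also higher in the arrays labelled KO of set 1, by 5.25, but differed by only 0.16 in set 2. The 6 genes were higher in KO in set 2 as well, though none passed there. Their set 2 differences were 1.95 (Cyp4a31), 2.20 (Cyp4a32), 1.24 (Hgd), 1.29 (Mup-ps14), 0.81 (Mup-ps6) and 1.58 (Mup-ps10). The KO-lower side was led by Cebpa and by small RNA genes. The 5S ribosomal RNA genes and pseudogenes n-R5s88, n-R5s28 and n-R5s102 differed by -0.63, -0.53 and -0.44. The genes n-R5s101, n-R5s114, n-R5s119 and n-R5s129 had identical values on every array, which differed by -0.44, and Snora31, a small nucleolar RNA, differed by -0.79. S1pr5, a sphingosine 1-phosphate receptor, differed by -0.76 and had the smallest p of all genes with the set as a block (8.56e-05, adjusted p = 0.984).

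Of the 30701 genes, limma with Benjamini-Hochberg adjustment called 0 without a block, 0 with the set as a block and 0 with the replicate number as a block. The counts at an unadjusted p under 0.05 were 38, 1480 and 1234, where a uniform spread of p would give 5% of the genes. Ordinary least squares without moderated variances also called 0. On simulated arrays with the same set difference, the fit without a block recovered 0 of 100 genes changed by 2 on the log2 scale, and the fit with the set as a block recovered 97 of 100, and 73 of 100 changed by 1. The simulated spread was that within set and genotype. For genes with a mean over 7 its median SD was 0.175, against 0.219 in the data with the set as a block. The recovery of that fit is therefore overstated for the data. Within set 1 no gene passed, and within set 2 the count was 1: Dbp, a clock-controlled transcription factor, fell by 2.59 (SE 0.16, adjusted p = 0.026) and was lower in both KO arrays than in either wild type array of that set. That fit takes its spread from all 8 arrays, and the arrays of set 2 fitted alone gave 0 genes (lowest adjusted p = 0.0686). KO and wild type values were parted in the same direction within both sets in 1628 genes, or 5.3%, where chance gives 5.56%.

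**Figure D2:**
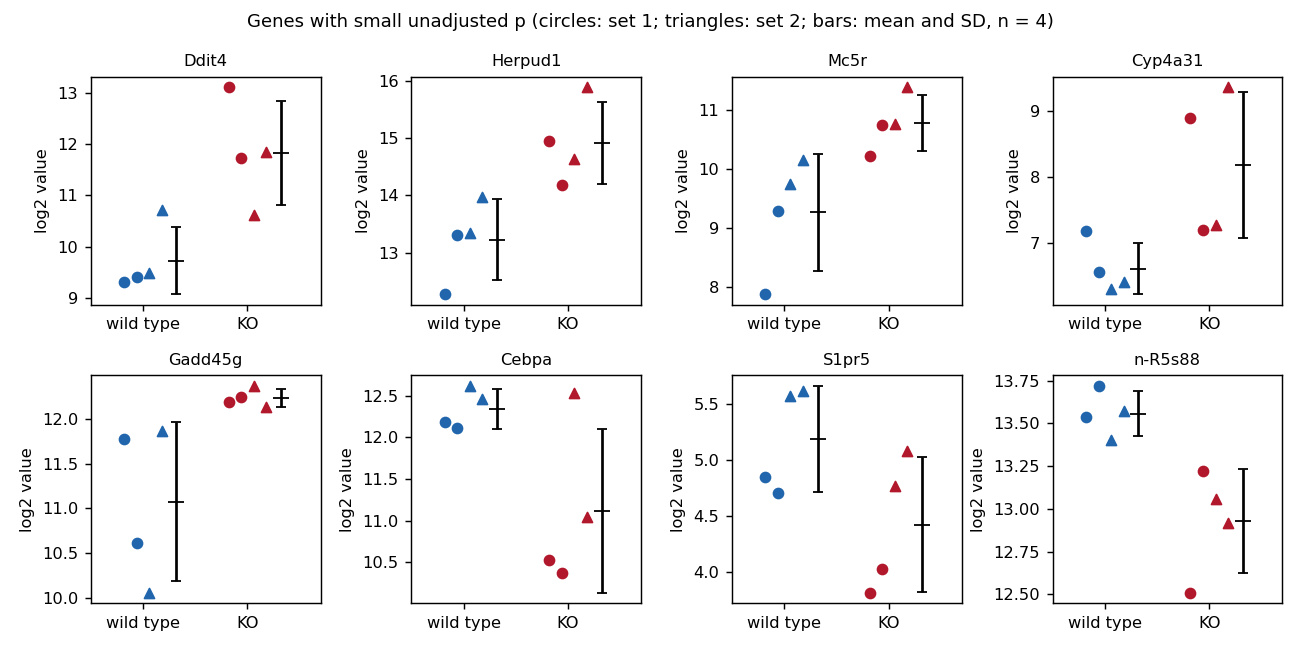
Log2 values of 8 genes with small unadjusted p, each point an array (circles set 1, triangles set 2), with the mean and SD of the 4 arrays of each group beside them. Herpud1 is higher in all 4 KO arrays than in any wild type array (14.92 against 13.23 on average), and Cebpa overlaps between the groups; none of the 8 passed the test.

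Some lists of lipid genes and the markers of skeletal muscle had medians below 0 in the arrays labelled KO, and camera called them at its preset correlation only. Their medians lay below 0 in set 2 and near or above 0 in set 1, and de novo lipogenesis and fatty acid uptake were not called. All 19 measured genes of cholesterol synthesis were lower, with a median difference of -0.24 (camera adjusted p = 2.82e-08 at the preset correlation; adjusted p = 0.943 with an estimated correlation). Msmo1, Sqle, Idi1 and Hsd17b7, enzymes of that pathway, differed by -0.69, -0.62, -0.70 and -0.56. With any 1 array left out the list kept its call (adjusted p up to 0.000746). Leaving out 1 array, here and for the lists below, unbalances the sets in a fit without a block, so the set difference enters such values. In the list of lipolysis and lipid droplet proteins, 23 of 31 members were lower and the median difference was -0.19 (adjusted p = 4.46e-06; adjusted p = 0.943 with an estimated correlation; adjusted p = 0.816 without KO replicate 4). Its members Fitm1, Plin5 and G0s2, a lipid droplet formation protein, a droplet coat protein and an inhibitor of adipose triglyceride lipase, differed by -0.74, -0.56 and -0.91, and Hsd17b13, which is abundant in liver, by 0.62. Markers of all adipocytes had 14 of 16 members lower, with a median of -0.16 (adjusted p = 9.34e-07; adjusted p = 0.943 with an estimated correlation; adjusted p = 0.19 without KO replicate 4), among them Cebpa, Dgat2 (-0.40), Plin1 (-0.62) and Lipe (-0.31).

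For each list that follows the adjusted p = 0.943 with an estimated correlation, beside the camera value at the preset correlation. Triglyceride synthesis had 14 of 18 members lower and a median of -0.10 (adjusted p = 0.0161), with Dgat2 at -0.40, Dgat1 at -0.37 and Gpat3 at -0.48, whereas Lpin1, a phosphatidate phosphatase, was at 0.81. Fatty acid oxidation had 25 of 36 members lower and a median of -0.07 (adjusted p = 0.0118), including Abcd3 (-0.32), Acot1 (-0.23) and Acot3 (-0.43), with Acsm3 at 0.43. Without KO replicate 4 camera placed fatty acid oxidation (adjusted p = 0.816) and the PPAR targets that follow (adjusted p = 0.525) above 0 instead of below. The sets were then unbalanced without a block, so this turn cannot be laid to that array alone. Within set 2 the mean of the fatty acid oxidation genes was 14.11 and 13.95 in KO, and 14.32 and 14.29 in wild type. The target genes of PPAR transcription factors had 21 of 28 members lower and a median of -0.12 (adjusted p = 0.00107), with Ppara at -0.81, Ucp3 at -0.91 and Plin5 at -0.56, whereas Cyp4a14, a fatty acid hydroxylase of liver, was at 3.43 (6.05 in set 1, where albumin was high, and 0.81 in set 2; 1.83 to 4.43 with 1 array left out, KO replicate 1 being highest at 13.37). Immediate early genes, which respond to stimuli within minutes, had 17 of 25 members higher and a median of 0.12 (adjusted p = 0.00354), led by Btg2 (0.48), Fosl2 (1.09), Ccn1 (1.52) and Klf6 (0.67). Triglyceride synthesis lost its call when any 1 of 4 arrays was left out, and fatty acid oxidation, PPAR targets and immediate early genes each lost theirs for any 1 of 3. All 33 skeletal muscle markers were lower, with a median of -0.56 (adjusted p = 1.16e-19, and adjusted p = 0.898 without KO replicate 3), among them Myh4 (-2.05), Atp2a1 (-2.11), Mybpc1 (-1.42) and Pgam2 (-0.42). In 7 of the genes named 1 array lay far from the 3 others of its group: wild type replicate 4 for Ddit4 (10.71) and Ccn1 (11.54), wild type replicate 2 for G0s2 (9.59), KO replicate 3 for Dgat1 (13.66) and Ucp3 (13.05), and KO replicate 4 for Lpin1 (16.91) and Plin2 (15.87).

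These 8 of 28 lists were called by camera at its preset correlation. With an estimated correlation 0 lists were called (adjusted p = 0.943 for each), and the rotation test fry called 0. Without a block the set difference can raise the estimated correlation. It was 0.412 for triglyceride synthesis, against 0.0407 with the set as a block, whereas for skeletal muscle markers it was 0.796 and 0.828. Without a block no member of any list passed on its own, over all genes or adjusted over the list alone. With the set as a block 9 lists were called, and 0 with an estimated correlation (lowest adjusted p = 0.681). Immediate early genes left them (adjusted p = 0.0533), and markers of macrophages (median 0.08, adjusted p = 0.0126) and of fibroblasts and preadipocytes (median -0.06, adjusted p = 0.0418) joined. Among macrophage markers 22 of 25 were higher, including Cd14 (0.49), Cd163 (0.24), Mrc1 (0.28) and Adgre1 (0.19), and among fibroblast markers 13 of 17 were lower, including Mfap5 (-0.32), Cd248 (-0.31), Islr (-0.22) and Dpt (-0.24). The replicate number as a block also gave 9 lists, and 0 with an estimated correlation (lowest adjusted p = 0.731). Without KO replicate 3 the count of lists without a block was 3, and without KO replicate 4 it was 2, both with unbalanced sets. After quantile normalization or median centring 5 of the 8 lists kept their call, and triglyceride synthesis, fatty acid oxidation and PPAR targets lost it.

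The 20 other lists did not pass without a block. Brown adipocyte identity and thermogenesis had a median of -0.027 (adjusted p = 0.086), the hypoxia response 0.028 (adjusted p = 0.56), nuclear-encoded oxidative phosphorylation -0.0024 (adjusted p = 0.609) and white adipocyte markers -0.13 (adjusted p = 0.247). Fatty acid uptake had a median of -0.057, de novo lipogenesis -0.0042, the TCA cycle -0.0019 and glycolysis -0.018, with adjusted p values of 0.269, 0.714, 0.714 and 0.704. The medians were 0.053 for interferon-stimulated genes, -0.024 for extracellular matrix genes, 0.0085 for clock genes and -0.014 for nerve and Schwann cell markers (adjusted p = 0.638 for each). Cell cycle genes stood at 0.0033 (adjusted p = 0.68), endothelial markers at 0.018 (adjusted p = 0.714) and blood markers at 0.028 (adjusted p = 0.269). The endoplasmic reticulum stress list had a median of -0.027, with 14 members higher and 15 lower, and a mean of 0.067 (adjusted p = 0.68). Median and mean also differed in sign for clock, glycolysis and TCA cycle genes, and the test of inflammatory cytokines (median 0.023, adjusted p = 0.68) and of lymphocyte markers (median 0.014, adjusted p = 0.749) pointed below 0.

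Within the sets the lists parted at the preset correlation of camera, and with an estimated correlation no list passed in either set (lowest adjusted p = 0.584 in set 1 and adjusted p = 0.228 in set 2). In set 2, 12 lists were called, 10 lower and 2 higher. The 10 lower lists included cholesterol synthesis with a median of -0.64 (adjusted p = 1.11e-08). Lipid droplet proteins stood at -0.60 (adjusted p = 8.4e-07), PPAR targets at -0.31, general adipocyte markers at -0.33 and fatty acid oxidation at -0.26, with skeletal muscle markers at -1.13, where KO replicate 3 alone lay below both wild type arrays in the mean of the markers. The 2 higher lists were immediate early genes (median 0.55, adjusted p = 2.56e-05) and endoplasmic reticulum stress genes (median 0.14, adjusted p = 0.00491), the second being lower in set 1 (median -0.11, adjusted p = 0.00763). When adjusted over the list alone, 11 of 19 cholesterol synthesis genes and 11 of 31 lipid droplet genes fell in set 2, and 0 of either did so over all genes. In set 1 cholesterol synthesis stood at -0.0099 (mean 0.091, adjusted p = 0.909) and lipid droplet proteins at 0.09 (adjusted p = 0.131). Fatty acid oxidation was higher there, with 27 of 36 members up and a median of 0.08 (adjusted p = 0.0398; adjusted p = 0.983 with an estimated correlation). Clock genes were higher in set 1 (median 0.20, adjusted p = 0.00763) and lower in set 2 (median -0.53, adjusted p = 0.00123), with Arntl at 0.02 and 1.69, Npas2 at 0.02 and 1.63, Tsc22d3 at 1.22 and 0.25, and Dbp at 0.28 and -2.59. The rotation test fry called 0 lists in set 1 and 1 in set 2, blood markers (adjusted p = 0.0261).

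**Figure D3:**
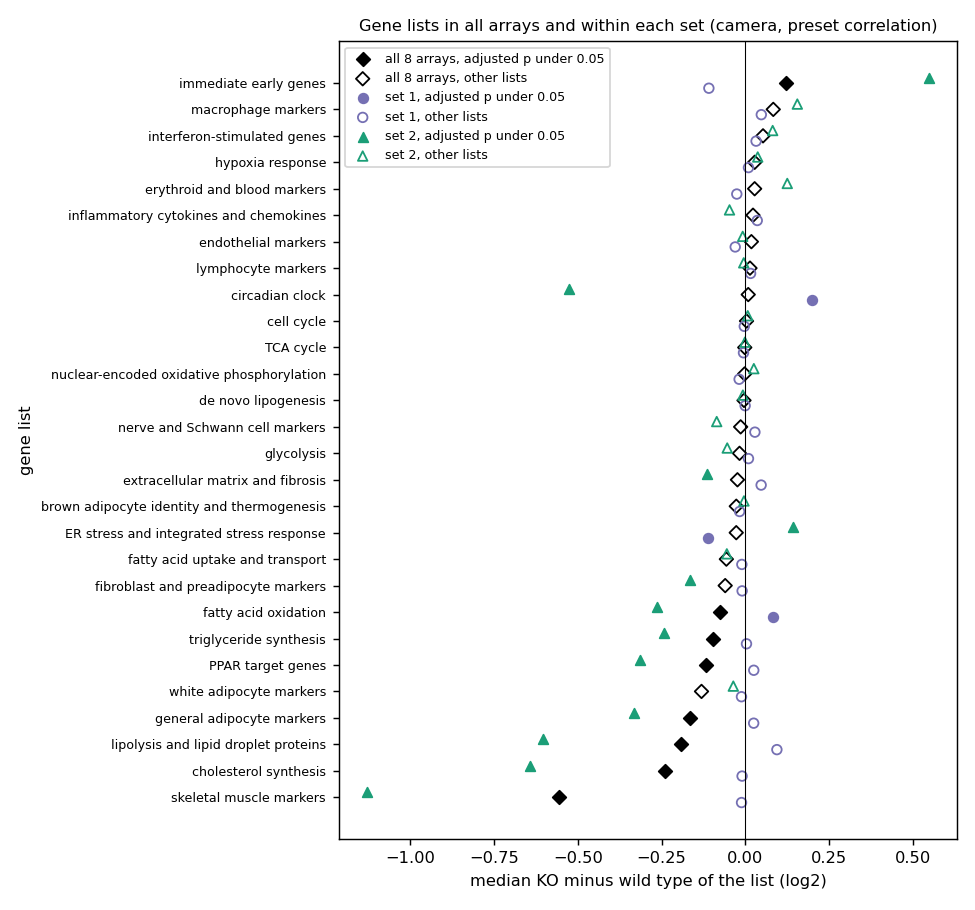
Median KO minus wild type difference (log2) of each of the 28 gene lists over all 8 arrays, in set 1 and in set 2; filled symbols mark lists called by camera at its preset correlation. Skeletal muscle markers lie at -0.56 over all arrays, -0.012 in set 1 and -1.13 in set 2, and clock genes lie on opposite sides of 0 in the sets.

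Over all arrays without a block, the reference genes of brown fat and lipid droplets did not differ by more than the spread, which holds the set difference. Ucp1 could not be compared. Pnpla2, the lipase that Hilpda is known to inhibit, read 18.77 ± 0.33 in KO and 18.69 ± 0.30 in wild type (SD, n = 4), and Lipe, hormone-sensitive lipase, read 15.31 ± 0.62 in wild type and differed by -0.31 (SE 0.34). The droplet protein Plin2 read 16.81 ± 0.63 and 17.18 ± 0.24. Ppargc1a, a coactivator of mitochondrial genes, read 13.70 ± 2.22 and 13.48 ± 0.98, and Dio2, the enzyme that activates thyroid hormone, 10.08 ± 3.75 and 11.38 ± 0.85, with Dio2 differences of -4.63 in set 1 and 2.02 in set 2 (adjusted p of the change = 0.0802). The differences were -0.16 for Pparg, -0.04 for the fatty acid transporter Cd36, -0.06 for lipoprotein lipase (Lpl) and -0.09 for adiponectin (Adipoq). Ucp1, the uncoupling protein of brown fat, stood within 0.1 of the highest possible value on all 8 arrays, so that neither a fold nor a lack of difference can be given. Without a block the adjusted p was 1 in limma for each of the other genes above. Within sets 1 and 2 Lipe differed by 0.11 and -0.73 (SE 0.19). Plin5 differed by -0.01 and -1.10 (SE 0.44), and Ppargc1a by -0.92 and 1.36 (SE 0.51). None of these 3 passed in limma within a set (adjusted p of at least 0.16).

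The KO minus wild type difference was then compared between the 2 sets, a comparison chosen after the data were examined. It differed for 153 genes in limma at an adjusted p under 0.05, higher in set 2 for 115 and lower for 38 (82 and 77 after quantile normalization). The count was 6 with trend and robust settings and 0 with ordinary least squares. Irf4, a transcription factor of thermogenic gene expression, stood at 9.21 in KO and 10.75 in wild type in set 1, and at 14.15 and 9.18 in set 2, a change of the difference by 6.51 (SE 0.85, adjusted p = 0.0461). The nuclear receptors Nr4a2 and Nr4a3, both immediate early genes, had differences of -2.06 and -1.26 in set 1 and 2.40 and 2.76 in set 2. Cyp2b10, a drug-metabolizing cytochrome, went from -1.66 to 3.50, and Slc3a2, the heavy chain of an amino acid transporter, from -2.64 to 1.49. Insig1, which retains sterol-sensing proteins in the endoplasmic reticulum, went the other way, from 2.79 in set 1 to -3.01 in set 2 (SE of the change 0.59, adjusted p = 0.0366).

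The same held for further genes. Ppp1r3c, a glycogen-targeting phosphatase subunit, went from 1.62 to -2.25, Otop1, a proton channel of brown fat, from 1.45 to -1.95, and Perm1, a regulator of mitochondrial genes in muscle, from 0.96 to -2.04. Lgr6, Trp53inp2, Nedd4l, Ltc4s, Hipk2, Fgd4 and Prkd1 also changed from above 0 to below 0, with set 2 differences of -2.35, -1.84, -1.54, -1.23, -1.73, -0.98 and -1.11. Plk3, Synm, Vnn1, Aspg, Rhou, Dpep1 and Kdm7a changed from below 0 to above 0, with set 2 differences of 2.77, 2.02, 2.59, 1.94, 2.22, 1.77 and 1.80. Of the fixed lists 9 members passed. Besides Otop1, Insig1, Vnn1, Dbp, Nr4a2 and Nr4a3 these were Mgll, monoglyceride lipase (0.72 and -1.34), Xbp1, a transcription factor of the unfolded protein response (-1.49 and 1.40), and Thbs1, thrombospondin (-0.19 and 1.56).

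For the same comparison camera called 11 lists, with an estimated correlation 0 (lowest adjusted p = 0.307), and fry called 1, endoplasmic reticulum stress genes (adjusted p = 0.0248). The 9 lists that moved down included lipid droplet proteins (median -0.62), cholesterol synthesis (-0.59), clock genes (-0.73) and skeletal muscle markers (-1.28), and immediate early genes (0.73) moved up. Endoplasmic reticulum stress genes also moved up in set 2 relative to set 1 (median 0.22, adjusted p = 0.000522; adjusted p = 0.307 with an estimated correlation), with Herpud1 at 1.79 and 1.59, Hyou1 at -0.81 and 0.04, Atf3 at -0.28 and 2.14, and Ppp1r15a at -0.11 and 0.77. Extracellular matrix genes moved down (median -0.20, adjusted p = 0.00221; adjusted p = 0.307 with an estimated correlation), with Sparc at 0.18 and -0.55, Loxl1 at -0.48 and -0.70, and Mmp2 at 0.40 and 0.02, whereas Thbs1, the one member that passed, moved up by 1.74 (adjusted p = 0.0366). Across the 7475 genes with a mean over 7, the differences of the 2 sets had a Pearson r of -0.40 and a Spearman rho of -0.446, and 32.8% of the genes had the same sign in both. Genes are not independent replicates. Leaving out any 1 of the 8 arrays leaves 1 array in a group of its set, so only the size of the change is given. It kept its sign in the 28 genes named here, such as Irf4 (5.58 to 7.43), Insig1 (-6.26 to -5.35) and Fgd4 (-2.53 to -2.30). These genes were named because they passed this same comparison, so the kept sign is no further support for it. With the skeletal muscle score as a covariate the count of 153 fell to 0. With that covariate the median absolute difference of the 28 genes named here was 3.29 (3.28 before), the median SE 0.404 (0.382 before) and the residual degrees of freedom 3 (4 before).

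**Figure D4:**
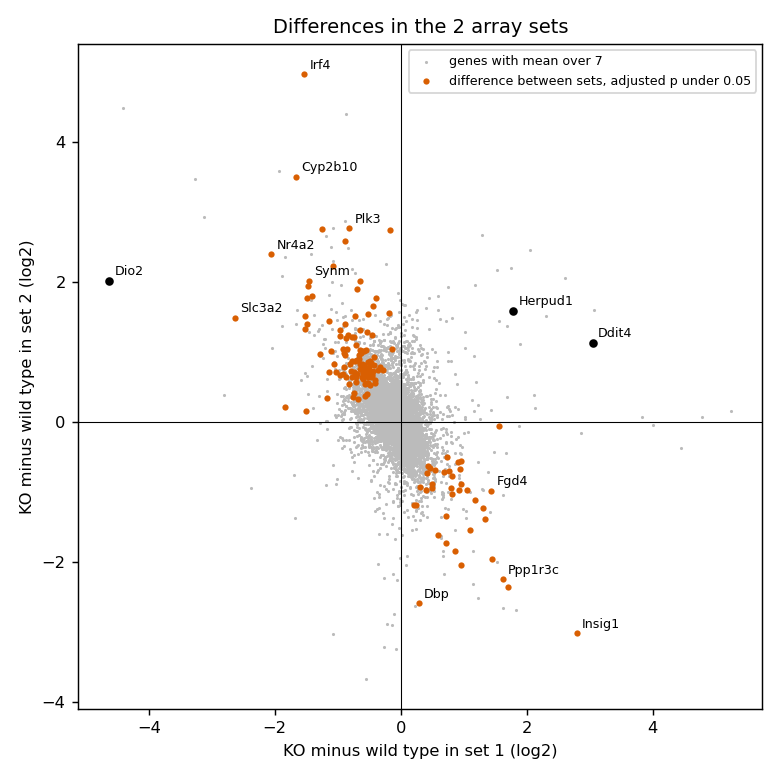
KO minus wild type difference (log2) in set 1 against that in set 2 for the 7475 genes with a mean over 7 (grey); orange points are the 153 genes of any level whose difference differs between the sets at an adjusted p under 0.05, and black points are 3 further named genes. Insig1 (2.79 and -3.01) and Irf4 (-1.54 and 4.97) lie in opposite corners, and Herpud1 (1.79 and 1.59) and Ddit4 (3.05 and 1.13) lie above 0 in both sets.

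Genes close to Hilpda on chromosome 6 were examined because strain differences around a targeted locus can appear as expression differences. Of 179 genes within 10 Mb, 0 passed in limma without a block and 0 with the set or the replicate number as a block. Since no gene passed anywhere in those fits, these counts say nothing about the locus. At an unadjusted p under 0.01 the counts near Hilpda were 0, against 2 of 30522 other genes without a block (two-sided Fisher's exact p = 1) and 226 with the set as a block (Fisher's exact p = 0.646). For the difference between the sets, 3 of the 179 passed (Hipk2, Kdm7a and Tmem140), against 150 of 30522 other genes. No test of these shares is given here. At an unadjusted p under 0.01 the counts were 12 of 179 against 1806 of 30522 (Fisher's exact p = 0.632).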

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

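The set block, the test of the difference between the sets and the clock test were chosen after the result was seen. The KO minus wild type difference differed between the array sets for 153 genes and 11 lists. Of the 18 splits balanced over the sets the real one alone gave as many genes, with 0 as the highest other value, and the splits are too few for a share under 0.05. Among the 34698 probe sets without 1 gene name, 1 passed with the set as a block (adjusted p = 0.0231) and 48 passed for the difference between the sets.

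Across genes the KO minus wild type differences of the sets opposed each other, with r of -0.446 over 7450 genes outside the muscle and liver lists. Differing amounts of muscle and liver RNA as the whole cause are argued against, since r was -0.386 with both scores as covariates, and -0.0487 with noise alone. Group labels exchanged in 1 of the sets stay open, because r corrected for noise between arrays was -0.74 over all 7475 genes with a mean over 7 (-0.40 uncorrected) and -0.755 over the 7450, between the bounds set for and against an exchange, and Hilpda does not settle it: its KO minus wild type difference was -0.40 in set 2, in the direction of the labels, and 0.09 in set 1. Arrays collected at different times of day stay open as well: Arntl, Npas2, Clock and Nfil3 against 7 clock genes of opposite phase gave a KO minus wild type contrast of -0.335 in set 1 and 2.25 in set 2, with -2.02 and -2.06 in the wild type arrays of set 2 and 0.0744 and 0.353 in the KO arrays. In set 1 the groups overlapped (1.17 and 0.132 in KO, 0.594 and 1.38 in wild type), so the opposite sign there lies within the spread. An effect of Hilpda loss that depends on a condition differing between the sets was not tested, as the labels name no such condition.

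The KO against wild type count without a block was 0, which any split reaches (35 of 35), so the splits say nothing about chance for it. The highest other was 27406, for the split that follows the array sets, which points to that structure, and the other splits balanced over the sets gave 0. For the lists, chance can not be excluded, since 22 of 35 splits called at least the 8 lists of the real one, with 16 as the highest other. Among the 18 splits balanced over the sets, 8 did so, the real one included, with 11 as the highest other. With the set as a block the real gene count was 0 as well, which all 18 splits reach. The highest other was 183, for the split with the groups exchanged in set 2, and the splits are too few for a share under 0.05. With the replicate number as a block the real count was 0, which all 8 splits that part same-numbered arrays reach, and the highest other was 5, again too few splits.

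In 7 of 268 groups of 4 values 1 array lay far from the others. Each group holds 2 arrays of each set, and a difference between the sets can hide an outlying array. The 13.4 that chance gives for 4 values of 1 distribution therefore cannot be set against the 7, and further outlying arrays are not excluded. The gap, as a share of the range, was 0.880 for Ddit4 in wild type (replicate 4), 0.901 for G0s2 in wild type (replicate 2), 0.841 for Ccn1 in wild type (replicate 4), 0.853 for Plin2 in KO (replicate 4), 0.869 for Lpin1 in KO (replicate 4), 0.855 for Dgat1 in KO (replicate 3) and 0.905 for Ucp3 in KO (replicate 3).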

How the results depend on the processing

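The set block, the within-set fits, the muscle score and the test of the difference between the sets were chosen after seeing the data; the cause of the changes below was not tested unless named. The count of 0 genes in KO against wild type stayed 0 under the filter, trend and robust settings, ordinary least squares, both normalizations, array weights, every probe set, an adjusted p under 0.1, the set block with or without quantile normalization or the muscle score, set 2 alone, and every array left out. The replicate block also gave 0, with or without quantile normalization, and ended 1 list call, that of immediate early genes (adjusted p = 0.0519), and added 2; the pairing changed no other call. Unadjusted thresholds gave 36 genes (fold of at least 1.5, 33 up and 3 down), 24 (fold of at least 2) and 2 (p under 0.01), and set 2 with the spread of all arrays gave 1. The 153 genes for the difference between the sets became 379 with the filter (152 shared), 82 with median centring, 6 with trend and robust settings, and 0 with ordinary least squares or with the muscle score. With that score the 28 genes named kept their median absolute difference (3.29, 3.28 before), with median SE 0.404 (0.382). Residual degrees of freedom were 3 (4). Some genes lost the call although their SE fell, such as Irf4 (0.854 to 0.777) and Prkd1 (0.27 to 0.184), so the reason for the lost calls is not settled. Leaving out 1 array gave 0 to 10. The 8 lists became 0 with an estimated correlation, fry or exact permutation, 6 with quantile normalization or median centring (5 shared), 7 with array weights, 5 with the filter, 5 with the set block and muscle score, 3 within set 1 and 12 within set 2, and 2 to 11 with 1 array left out. The smallest p of the exact permutation is 0.0286, so a few lists alone could not pass it after adjustment over all lists. Within set 1 the direction given by camera, which sets a list against all other genes, turned for 7 lists, although the median of skeletal muscle markers stayed below 0 (-0.012) and triglyceride synthesis had 9 members higher and 9 lower. The adjusted p values were 0.131 (lipid droplet proteins), 0.941 (triglyceride synthesis), 0.0398 (fatty acid oxidation), 0.230 (PPAR targets), 0.131 (immediate early genes), 0.909 (skeletal muscle) and 0.662 (general adipocyte markers). Quantile normalization and median centring ended the calls of triglyceride synthesis (adjusted p = 0.18 and 0.17), fatty acid oxidation (0.18 and 0.17) and PPAR targets (0.0679 and 0.17), the filter ended the same 3 (0.0557, 0.139 and 0.0593), and array weights ended fatty acid oxidation (0.0642). The set block with the muscle score ended fatty acid oxidation (0.0588), PPAR targets (0.0665), immediate early genes (0.204; 0.0533 with the set block alone) and skeletal muscle (0.962). With 1 array left out, adjusted p ranged from 1.85e-07 to 0.816 for fatty acid oxidation, 1.18e-10 to 0.525 for PPAR targets, 7.28e-11 to 0.816 for lipid droplet proteins, 0.001 to 0.816 for triglyceride synthesis, 2.13e-08 to 0.68 for immediate early genes, 2.82e-44 to 0.898 for skeletal muscle and 1.88e-11 to 0.19 for general adipocyte markers, and cholesterol synthesis kept its call. Fatty acid oxidation and PPAR targets turned to higher in KO without KO replicate 4. Differences that changed sign with 1 array left out ranged from -0.45 to 0.13 for Hilpda, -0.053 to 0.17 for Pnpla2, -0.46 to 1.06 for Ppargc1a, -0.14 to 0.058 for Cd36, -0.16 to 0.0056 for Lpl, -0.37 to 0.21 for Adipoq, -0.42 to 0.043 for Sparc, -0.048 to 0.49 for Mmp2, -0.12 to 0.57 for Cd163, -0.13 to 0.66 for Mrc1, -0.054 to 0.51 for Adgre1, -0.74 to 0.015 for Cd248, -0.54 to 0.13 for Islr and -0.73 to 0.22 for Dpt. Without a block, leaving out 1 array unbalances the sets, so the set difference enters the ranges given here for genes and lists. Hilpda turned positive without KO replicate 1 or 2, which read low, and without wild type replicate 3 or 4, which read high. Adipoq differed by 0.0063 within set 1 and -0.18 within set 2. Ucp1 also changed sign (-0.028 to 0.055, and -0.011 with median centring), which says nothing about stability, as it stood at the ceiling of every array. The other genes run under these settings, which did not include Alb, Apoa1, Mup20 and Mup3, kept their direction under every setting run over all arrays. The size of many varied with 1 array left out, such as 0.093 to 0.89 for Hsd17b13, -2.74 to -0.12 for Dio2 and -0.63 to -0.0089 for Mfap5. Of the 28 genes named for the difference between the sets, 28 passed with the filter, 27 with array weights, 26 with quantile normalization, 16 with median centring and 3 with trend and robust settings.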

Other observations

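The liver and sex-linked tests below were chosen after the result was seen, apart from the share of unseen liver genes, and the genes of the next sentences were picked after their values were seen. In set 2, where albumin and the apolipoprotein Apoa1 differed by 0.16 and 0.07 between KO and wild type, some other genes of liver repertoire differed by more. Mup20 and Mup3, major urinary proteins, read 5.69 and 5.14 in KO replicate 3, 6.92 and 6.44 in KO replicate 4, and 4.00 to 4.44 in the wild type arrays of set 2, differences of 2.05 and 1.60. Cyp4a31 and Cyp4a32 differed there by 1.95 and 2.20, and Hgd by 1.24. Each of these genes missed the threshold in set 2 (adjusted p from 0.289 for Cyp4a31 to 0.674 for Mup3).

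Liver transcripts stood out on the arrays of set 1. Induction of liver genes by loss of Hilpda is argued against for the group as a whole, since the median KO minus wild type difference of 49 liver genes was 0.0677 in set 2, against 1.16 in set 1. Separate normalization of the sets is argued against, because the median of these genes spanned 2.83 among the 4 arrays of set 1, which share a distribution. Liver RNA mixed into these samples stays open as a candidate explanation, because 98% of the 49 genes, chosen without their values being seen, had their highest value on the array with the highest albumin; 8 of the 49 also lay above the olfactory receptor 95th percentile on the arrays of set 2.

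The Y-linked transcripts went against the label of female mice. Background on their probe sets is argued against, since the lowest of 3 broadly expressed Y-linked genes lay at least 3.67 above the olfactory receptor median on each array. Samples taken from male mice stay open, because 8 of 8 arrays had these genes high with Xist under the olfactory receptor 95th percentile. Male RNA mixed into samples from females cannot be told apart by these values: Xist lay at most -0.274 from that percentile, near the floor of the arrays, and whether its probe set measures the transcript was not tested.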
